A study of Mus musculus with 400 samples.

How the data were processed

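The data were the transcriptomes of 400 single cells of 1 sorted population, the Lgr5-high cells of the mouse small intestine. Per the labels' protocols, crypts were isolated from the duodenum and jejunum of mice that carry a green fluorescent protein at the Lgr5 locus, dissociated with EDTA and dispase, stained with DAPI to leave out dead cells, and sorted by flow cytometry. Single cells were captured on a microfluidic chip (Fluidigm C1, high-throughput format), and cDNA was made and amplified with a SMARTer kit, per the labels' protocols. The sample titles carry a set number from 1 to 10 and a barcode number, with 40 cells in each set. The set number was used here as a technical split, called the library set. The labels name no animal for any cell, so the population was treated as 1 sample. Cells are not replicates, and no p-value, standard error or number of changed genes was computed from them.

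The deposited table held a whole number for each of 33496 genes in each cell, and these values were used as counts, not normalized. The genome build was GRCm38.p4, per the submitters' processing notes. The aligner, the counting tool, the gene annotation release, the use of strand and the use of molecular identifiers (random tags that mark each captured molecule) are not given in the sources used here. The deposited counts reached at most 36 for any gene in any cell, and the values of the most abundant genes lay close together below that maximum. Ratios of abundant genes are therefore compressed on this scale, and ratios of genes with few counts are less affected. The protocol in the labels mentions spike-in RNA, and the table had 0 rows with a spike-in name, so no spike-in scaling was made. No pair of cells had identical columns.

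Gene symbols and positions came from GENCODE M21, which uses the same build. A symbol was found for 33219 of the gene identifiers, of which 25822 had the same identifier version, and 277 identifiers had none. Another 27 rows repeated a symbol already in use. Of the 44 genes named by rule, 13 have exons that overlap an exon of another annotated gene. Without a stated use of strand, counts of such pairs, of antisense genes and of pseudogenes that share sequence with their parent genes are uncertain.

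Cells were kept with at least 10000 counts, at least 1000 genes with a count and under 20% of counts from the mitochondrial genome. This left 380 cells, and the 20 cells left out all had fewer than 10000 counts. Doublets were not removed, and 1 alternative left out the 5% of kept cells with the most genes. CPM, the usual depth-scaled count, was computed from all gene counts of a cell. To compare shares of cells across depths, each cell was thinned at random, without replacement, to 19169 counts, the 10th percentile of kept cells, and the 38 shallower cells were left out. Of those 38 cells, 5 had a Mex3a count at full depth.

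Cells with 1 count or more of Mex3a after thinning (33 cells) were compared with the other 309 cells. Cells called without Mex3a are thus those with no count after thinning. Thinning removed the Mex3a counts of some of them, and mean full-depth Mex3a was 64.7 CPM in the 33 cells and 1.21 CPM in the 309. These classes are gates within 1 population. For each gene, the log2 ratio of mean full-depth CPM (cells with over cells without Mex3a) was computed with a pseudocount of 1 CPM. The value of a gene list was the median log2 ratio over members with a count in at least 5% of kept cells. Each list value was placed among 10000 random lists of the same size and matched mean CPM, among 200 control gates, and beside its standard deviation (SD) over library sets with at least 3 cells in each class (9 sets). Those sets held at most 4 cells with Mex3a each. A gene with few counts can have none in so few cells, which pulls its set values and set directions below 0. A control gate splits the same 342 cells by another gene detected in a like share of them, here in 32 to 34 cells, and a gate gene was never counted as a list member. Single genes were ranked among 14256 genes with a count in at least 10% of kept cells and a mean of 10 CPM or more in either class. Shares of cells have exact Clopper-Pearson binomial intervals, at 95%. Where a class had few counts of a gene, the log2 ratio of summed counts, scaled by the total counts of each class, is given with the exact binomial interval of its 2 counts. For 0 counts in a class, the upper limit of that interval is given and no fold.

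A cell cycle score was the sum of the mean log2(CPM + 1), after thinning, over an S phase list and a G2 and M phase list, and cells were ranked into tertiles by it or by Lgr5 CPM. Cells were clustered with scanpy 1.11.5 and the Leiden method in igraph 0.11.9 (log of counts per 10000, 1000 variable genes, 15 principal components, 15 neighbours, resolution 0.6), with Mex3a, ribosomal protein and mitochondrial genes left out of the variable genes. A cluster's defining genes were the 10 with the highest fold over other cells among genes in at least 25% of its cells. Other software was python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19 and matplotlib 3.10.9.

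The filters, gates, thinning depth, 28 gene lists, cell type markers, cluster settings and naming rule were chosen before the data were examined. The lists were epithelial, intestinal stem cell, reserve stem cell, S phase, G2 and M phase, cell cycle brakes, ribosome biogenesis, translation factors, glycolysis, fatty acid oxidation, Notch, BMP and EGF receptor pathways, dissociation and stress, p53 targets, ribosomal proteins, nuclear genes of the respiratory chain and the mitochondrial genome, and markers of Paneth, goblet, enteroendocrine, tuft, enterocyte, immune, stromal, endothelial, red blood and enteric glia cells. Only lists with at least 3 measured members were given a value, which held for 26 lists. The genes named for the Mex3a comparison were 23 fixed genes, up to 4 extreme members of each list with a mean of 10 CPM or more, and the 10 highest and 10 lowest log2 ratios among genes with the same direction in at least 80% of the sets.

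The comparison was tested on simulated data, in which 50 genes each were set to log2 ratios of 2, 1, −1 and −2 among 13761 genes in classes of the real sizes. The median recovered values were 1.97, 0.93, −0.94 and −1.91, and all 50 genes of each size had the right direction. A simulated log2 ratio of −0.5 in the 51 genes of the G2 and M phase list was recovered as −0.48. The simulated cells had known classes, counts drawn around 1 mean profile and no ceiling on counts. The test therefore checks the calculation, not whether such a difference would be seen where 1 count decides the class. Alternatives to the depth, random draw, gate, filters, pseudocount, level, list value, score, clustering and marker thresholds were tried, and each library set was left out in turn. Further alternatives were added after the data were seen, namely 20 random draws of the thinning, counts mapped back through a simulated merging of identifiers, a higher Mki67 threshold, and leaving out a cluster or cells rich in other markers.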

Results

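The series measured mRNA in 400 single Lgr5-high cells of the mouse small intestine. Lgr5 encodes a receptor that enhances Wnt signalling and marks the cycling stem cells at the crypt base. By its title, the study concerns Mex3a, which encodes an RNA-binding protein, and names it as the mark of a part of these cells that divides slowly. All cells belong to 1 group with no animal named, so there was no replicate check at the level of mice, and every SD below is over library sets. That SD is a technical spread that also holds differences between the few cells of a set. Total counts ranged from 4491 to 70133 per cell, with a median of 31727.5, and a median of 8547 genes had a count. Among the 380 cells kept, totals ranged from 10766 to 70133, with a median of 32112. The mitochondrial genome took at most 2.47% of counts in these cells. The 20 cells left out had totals of 4491 to 9841 and a median mitochondrial share of 2.56%. The mitochondrial ribosomal RNA mt-Rnr2 had the highest mean count, 30.3 over the 400 cells, with a variance of 3.41. All 6 genes with a mean count of 25 or more had a variance below their mean.

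**Figure D1:**
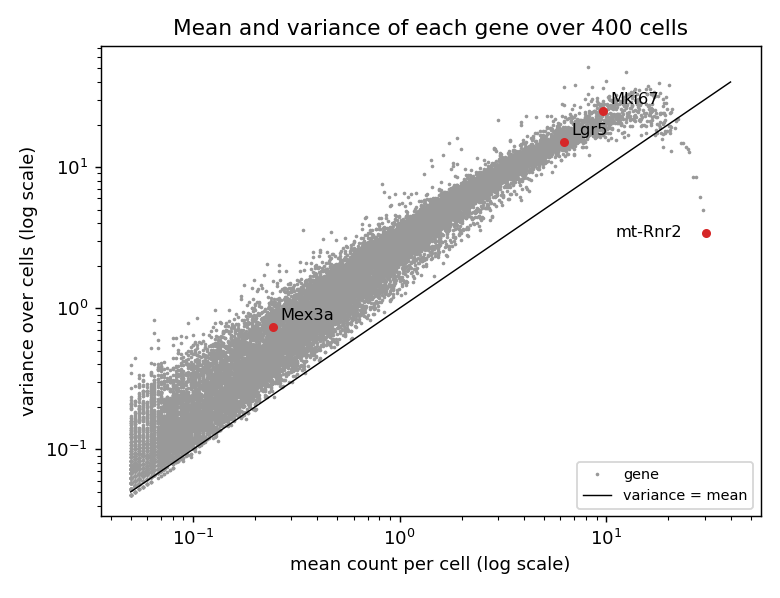
Mean (x axis, counts per cell) and variance over cells (y axis, counts squared) of each gene in the 400 cells, with the line on which the variance equals the mean; both axes are logarithmic. mt-Rnr2, with a mean of 30.3 counts and a variance of 3.41, lies far below the line, as do the other 5 genes with a mean of 25 counts or more.

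Mex3a (ENSMUSG00000074480.4; GRCm38 chromosome 3, 88532395 to 88541396, plus strand, protein-coding) had a count in 47 of 380 cells, or 12.4% (95% interval 9.23 to 16.1). It had 1 count in 29 of these cells, at most 6 counts, and 3 counts or more in 3.42% of cells (1.83 to 5.78). At the thinned depth of 19169 counts, 33 of 342 cells, or 9.65% (6.74 to 13.3), had a Mex3a count. The share at full depth was 12.3% ± 3.54 (mean and SD over 10 library sets) and ranged from 5.41% to 17.9%. These intervals, and all others given for shares and counts, cover counting error only.

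The 5 stem cell genes named next were found in most cells, and 16 of the 22 genes of the stem cell list were in at least 90% of cells. Lgr5 had a count in 97.9% of cells (mean 6.51 counts), Olfm4, a secreted glycoprotein of crypt base cells, in 97.9% (6.08), Smoc2, a matricellular protein, in 100% (9.35), Axin2, a Wnt target, in 93.4% (5.56), and Ascl2, a Wnt-controlled transcription factor, in 91.1% (5.15). Genes of dividing cells were also found in most cells. Mki67, which encodes the proliferation antigen Ki-67, had a count in 99.2% of cells (mean 10.0 counts), Top2a, the topoisomerase of mitosis, in 100% (13.9), Ccnd2 in 100%, Ccnd1 in 91.8%, Ccnb1 in 88.9%, Pcna, the DNA polymerase clamp, in 86.1% and Myc in 59.2%. Of the genes linked to reserve stem cells, Hopx had a count in 98.7% of cells, Lrig1 in 91.1%, Bmi1 in 38.7% and Tert in 6.32%. The brakes of the cell cycle Cdkn1b (p27) and Cdkn1a (p21) had a count in 56.1% and 21.1% of cells. As background, genes of cell types that the sort should lack had a count in 0.263% (Cd8a), 2.89% (Col1a1), 4.74% (Alpi), 10.3% (Cd3e), 28.4% (Ptprc) and 44.5% (Pecam1) of the same cells. The share for Mex3a lay within this range, so a share of this size is not by itself evidence of Mex3a expression in those cells.

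The main question was whether cells with Mex3a show less of the cell cycle program. Mki67 had a count in all 33 cells with Mex3a, or 100% (89.4 to 100), and in 98.7% (96.7 to 99.6) of the 309 cells without it at the thinned depth, a difference of 1.29 points (SD over 9 sets 1.77). Top2a had a count in 100% (89.4 to 100) and 99.4% (97.7 to 99.9). Pcna had a count in 63.6% (45.1 to 79.6) of cells with and 79.6% (74.7 to 84.0) of cells without Mex3a, a difference of −15.98 points. It was lower in 7 of 9 sets, with a mean of −18.8 points and an SD of 19.6, and the intervals of both shares overlap. Because Mki67 was found in nearly all cells, a threshold of 5 counts was added after the data were seen. It was passed by 60.6% (42.1 to 77.1) of cells with and 67.0% (61.4 to 72.2) of cells without Mex3a, a difference of −6.38 points against an SD over sets of 14.4. In mean level, Mki67 reached 304 CPM in cells with and 315 CPM in cells without Mex3a (log2 ratio −0.05, SD over sets 0.15), and Top2a 438 and 436 CPM (0.01, SD 0.29). With counts mapped back through a simulated merging of identifiers the Mki67 ratio was 0.12, so its direction depends on the scale of the counts. The log2 ratio was −0.17 for the mitotic cyclin Ccnb1 (SD 0.73), −0.02 for Ccnd1 (SD 0.49), −0.02 for Ccnd2 (SD 0.16) and −0.03 for Myc (SD 1.09). Over 20 other draws these ranged from −0.44 to −0.13, −0.19 to 0.02, −0.08 to 0.01 and −0.49 to 0.03. The values used lay above 19, 16, 12 and 17 of those draws, against 7 for Mki67 and 7 for Top2a. Pcna, with 144 CPM in both classes, lay at 0.0012 (SD 0.61), and 20 other random draws of the thinning gave −0.50 to −0.07. Each of these differences was smaller than its SD over library sets. A set held at most 4 cells with Mex3a, so that SD also holds the variation between single cells. A difference smaller than it is not excluded.

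The lists of proliferation genes differed by less than their spread between sets. The S phase list had a median log2 ratio of 0.02 (24 of 41 genes above 0), but its mean over sets was −0.21 (SD 0.32, positive in 2 of 9 sets), and 4 of 20 other draws were above 0 (−0.10 to 0.08). Its members lay between the flap endonuclease Fen1 at 0.53 and the helicase gene Brip1 at 0.52, and the replication licensing factor Cdc6 at −0.84 and Casp8ap2 at −0.55. The G2 and M phase list had a median of 0.09 (35 of 51 above 0, SD 0.12), with the mitotic kinase genes Nek2 at 0.56 and Bub1 at 0.48, Gtse1 at −0.68 and Kif2c at −0.27. This median was −0.03 with thinning to the 25th percentile of depth and −0.05 without the cluster of cells with the most genes, and 20 other draws gave −0.09 to 0.03. Cell cycle brakes had a median of 0.07 (6 of 11 above 0) and a mean over sets of −0.43 (SD 0.57, positive in 1 of 9 sets), with the antiproliferative gene Tob1 at 0.49 and Rb1 at 0.22, and Rbl2 at −0.48. Cdkn1a, with 5 counts in the cells with Mex3a, lay at −1.40 (4.48 against 13.4 CPM, SD 1.70, lower in 9 of 9 sets), and 6 of the 200 control gates gave a lower value. Over 20 other draws its ratio ranged from −1.54 to 0.00. With so few counts over 9 sets, a set without a count lies lower by construction, so the number of sets is weak support. The same effect pulls down the set means of the S phase and brakes lists, whose members had few counts. Cdkn1b lay at 0.08 (SD 1.26).

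Ribosome biogenesis genes were higher in cells with Mex3a, with a median log2 ratio of 0.16 (19 of 22 genes above 0). With 3 counts or more of Mex3a as the gate (12 against 300 cells) this median was 0.03, and without the cluster of cells with the most genes it was 0.07. The RNA polymerase I factor Rrn3 lay at 0.69 and the 60S assembly factor Nip7 at 0.61, while Rrp9 lay at −0.31 and Polr1b at −0.13. The list stood at the 99.6th percentile of random lists and was positive in 7 of 9 sets. The mean over sets was 0.11 with an SD of 0.16, so the difference was no larger than the spread between sets, and 20 other draws gave 0.07 to 0.22. The list also lay above all 200 control gates (95% of gates −0.36 to 0.11). Those gates are a skewed comparison, since they tended to take cells with more genes (a median difference of 549 genes, against −203 for Mex3a), and in the cluster of cells with the most genes the list lay at −0.32. Their median was −0.13, so a place above them is in part set by how the gates were chosen. Fatty acid oxidation genes had the same median, 0.16 (11 of 16 above 0), and were also above all 200 control gates, with the mitochondrial trifunctional protein subunit Hadhb at 0.44 and Acadvl at 0.35, and Acot1 at −0.18. Pdk4, the kinase that restrains pyruvate dehydrogenase, had 1 count in cells with Mex3a and 125 in cells without, a depth-scaled log2 ratio of summed counts of −3.78 (−9.09 to −1.28). Over sets the fatty acid oxidation list was positive in 3 of 9 sets (mean −0.03, SD 0.11), and with 3 counts or more of Mex3a as the gate its median was −0.03. Over 20 other draws its median was 0.05 to 0.17, and 19 of the 20 lay below the value given here, with a middle value of 0.10 that lies inside the range of the control gates. These were the 2 lists of 26 outside that range in the draw used.

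Other growth and metabolism lists differed by less. Translation factors had a median of 0.03 (14 of 17 above 0, SD 0.09), with Eif3a at 0.19, Eif3b at 0.15, Eif4a1 at −0.08 and Eif2s1 at −0.17. Ribosomal protein genes had 0.02 (63 of 85, SD 0.15), at the 1.21th percentile of random lists, with Rps6 at 0.60, Rpl7a at 0.39, Rps4l at −0.16 and Rpl15 at −0.18. Glycolysis genes had 0.09 (11 of 15, SD 0.24), with Pgam1 at 0.50, the glucose transporter Slc2a1 at 0.47, and the phosphofructokinases Pfkl at −1.39 and Pfkp at −0.55. Nuclear genes of the respiratory chain had 0.09 (51 of 62, SD 0.16), with Ndufb4 at 0.34, Ndufs3 at 0.29, Ndufs4 at −0.15 and Cox7a1 at −0.68, and stood at the 98.4th percentile of random lists. All 20 other draws lay below this value (−0.01 to 0.08, middle value 0.05), so the percentile belongs to an extreme draw. Genes of the mitochondrial genome had a median of −0.06 (13 of 15 below 0, SD 0.14), below all random lists, and other draws gave −0.05 to 0.01. Members ranged from mt-Atp8 at 0.09 and mt-Nd4l at 0.05 to mt-Atp6 at −0.11 and mt-Nd6 at −0.56. Many of these genes had counts close to the maximum, where a higher total by itself lowers the CPM, and median totals were 34856 with and 32851 without Mex3a.

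Signalling and stress lists showed no common direction. Notch pathway genes had a median of −0.05 (4 of 10 above 0, SD 0.45), with Notch2 at 0.68, Jag1 at 0.43, Adam10 at −0.45 and Lfng at −0.59. BMP pathway genes had 0.10 (4 of 8, SD 0.51), with the BMP targets Id3 at 0.49 and Id1 at 0.41, Smad4 at −0.20 and the inhibitor Smad6 at −1.02. Other draws gave −0.19 to 0.09 for this list, and 6 of 20 were above 0. EGF receptor pathway genes had −0.02 (4 of 9, SD 1.15), with Spry2 at 0.57, Erbb2 at 0.26, the ligand gene Areg at −0.30 and Etv5 at −1.39. Dissociation and stress genes had 0.02 (9 of 15, SD 0.20), with the heat shock gene Hspa1b at 0.28, Egr1 at 0.18, Hspa1a at −0.25 and Dusp1 at −0.62. The heat shock genes Hspa1a and Hspa1b are near-identical copies, so their separate values are uncertain. Targets of p53 had −0.26 (2 of 9, SD 1.11), with Gdf15 at 0.55, Ccng1 at 0.02, Eda2r at −0.77 and Trp53inp1 at −0.90.

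**Figure D2:**
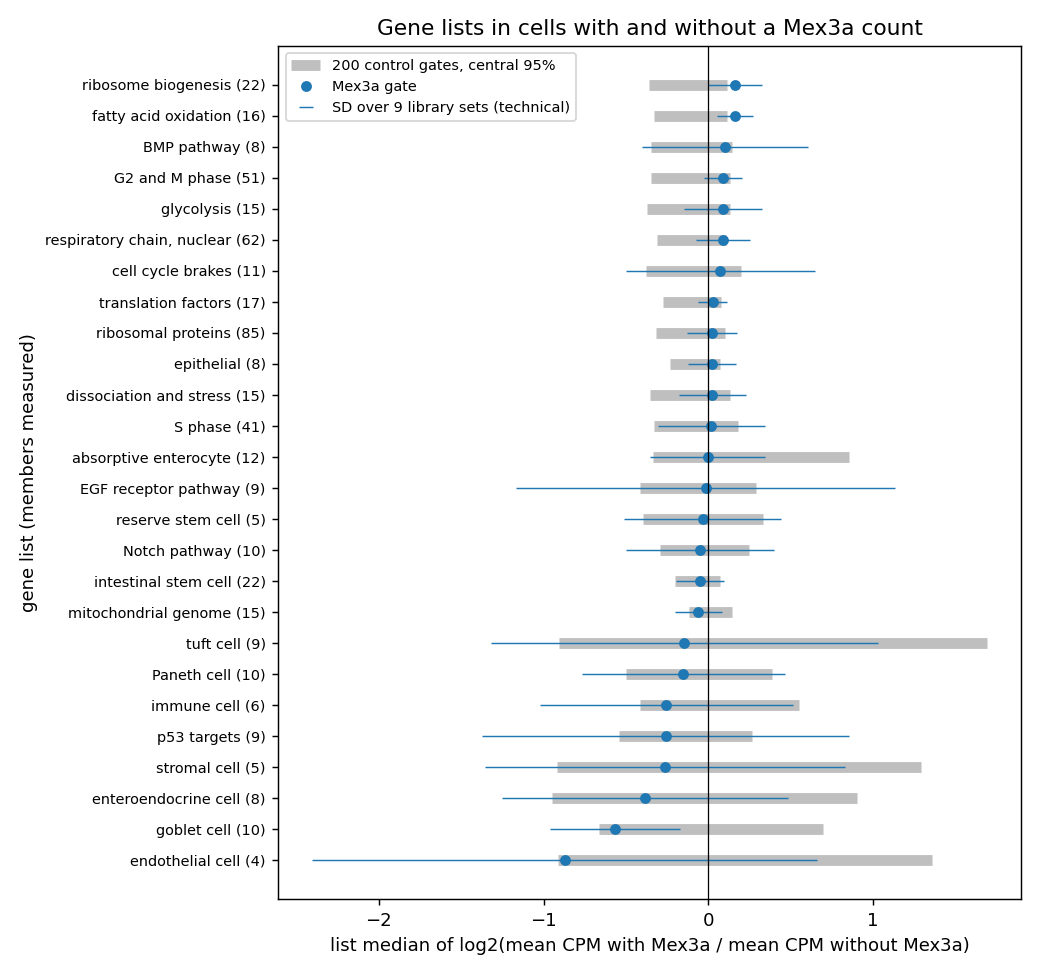
Median log2 ratio of mean full-depth CPM (x axis) of each gene list in cells with over cells without a Mex3a count after thinning. The 26 lists with at least 3 measured genes are shown (y axis), beside the range of 95% of the 200 control gates. The ribosome biogenesis and fatty acid oxidation lists, at 0.16 each, lie above that range, and the S phase (0.02) and G2 and M phase (0.09) lists lie within it.

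Stem cell genes were at a like level in both classes. Lgr5 (ENSMUSG00000020140.15; chromosome 10, 115450311 to 115587780, minus strand) had 210 CPM in cells with and 204 CPM in cells without Mex3a, a log2 ratio of 0.04 (SD over 9 sets 0.38). The intestinal stem cell list had a median of −0.05 (10 of 22 genes above 0, SD 0.14), with the gastrokine Gkn3 at 0.19, Soat1 at 0.14, the crypt transcription factor Sox9 at −0.20 and the Wnt antagonist Znrf3 at −0.30. Within it, Axin2 lay at 0.08, Olfm4 at −0.04, Smoc2 at −0.06 and Ascl2 at −0.18. The list stood at the 0.470th percentile of random lists and inside the range of the control gates (−0.20 to 0.07). That percentile belongs to the draw used, since other draws gave −0.09 to 0.04 with a middle value of −0.01, and 1 of 20 lay lower. Reserve stem cell genes had −0.04 (2 of 5 above 0, SD 0.48). Of these, Bmi1, a Polycomb gene, was higher at 47.8 against 31.95 CPM (log2 ratio 0.57, SD 1.08, higher in 5 of 9 sets), Hopx lay at 0.06 (SD 0.39), Lrig1, an EGF receptor antagonist, at −0.04 (SD 0.33) and Krt15 at −0.95 (SD 1.58). All 20 other draws gave lower values for Bmi1 (0.11 to 0.54) and higher ones for Hopx (0.08 to 0.30). The values of these 2 genes thus belong to an extreme draw. Tert, the telomerase catalytic subunit, had 0 counts in the 33 cells with Mex3a and 29 in the 309 without, and the exact interval allows a log2 ratio of up to 0.30, so no difference is shown. Across tertiles of Lgr5 CPM (114 cells each, mean Lgr5 92.4, 195 and 328 CPM from lowest to highest), the share of cells with Mex3a at the thinned depth was 7.89% (3.67 to 14.5), 11.4% (6.21 to 18.7) and 9.65% (4.92 to 16.6). Mean Mex3a was 5.70, 8.55 and 7.77 CPM, and all 3 intervals overlap.

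Most lists of markers of other cell types had medians below 0 in cells with Mex3a, at low counts. Most random lists of the same size and level also did: their medians of −0.49 for the enteroendocrine, −0.24 for the tuft, −0.45 for the stromal and −0.05 for the enterocyte list lay below the values of the lists themselves. The random medians for the Paneth (0.01), goblet (−0.08), immune (−0.08) and endothelial list (−0.30) lay above the values of those lists. Of the marker lists in this paragraph the goblet list alone stood outside the central 95% of random lists, at the 0.820th percentile. Goblet cell genes had a median of −0.56 (9 of 10 below 0, 0 of 9 sets positive, set mean −0.97, SD 0.39), while 20 other draws gave −0.59 to −0.08 with a middle value of −0.23. The set mean and set directions of these low counts are pulled below 0 by the few cells with Mex3a per set. In the draw used, members lay apart, with Fcgbp at −0.63, Agr2 at −0.50, the mucin gene Muc2 at −0.05 and Tff3 at 0.15. Paneth cell genes had −0.15 (8 of 10 below, SD 0.62), with lysozyme Lyz1 at −0.16, Ang4 at −0.56, Mmp7 at −0.53, Itln1 at 0.0049 and Pnliprp2 at 0.07, and other draws gave −0.09 to 0.24 for Lyz1. Enteroendocrine genes had −0.39 (5 of 8 below, SD 0.87), and Chga had 2 and 17 counts in the classes, a depth-scaled log2 ratio of summed counts of 0.10 (−3.06 to 2.17). Tuft cell genes had −0.15 (7 of 9 below, SD 1.18), though Pou2f3 lay at 0.29, and other draws gave −0.96 to 0.01 for the list, with a middle value of −0.75. Dclk1 lay at −0.78 (25.2 against 43.9 CPM, SD 1.58, lower in 8 of 9 sets), and 5 of 200 control gates gave a lower value. Enterocyte genes had −0.0040 (6 of 12 below, SD 0.35) and −0.38 to −0.02 in other draws, with Apoa1 at 0.40, Fabp2 at 0.34, Anpep at −0.82 and Lct at −1.17. Immune cell genes had −0.26 (6 of 6 below, SD 0.77), with H2-Aa at −0.07, Cd74 at −0.19, Ptprc at −0.70 and Cd52 at −1.08. Stromal genes had −0.26 (4 of 5 below, SD 1.09), and endothelial genes −0.87 (4 of 4 below, SD 1.53), with Emcn at −0.30 and Pecam1 at −0.70. The secretory lineage factor Atoh1 had 1 and 56 counts, a depth-scaled log2 ratio of summed counts of −2.62 (−7.95 to −0.08). Epithelial genes had 0.02 (4 of 8 above 0, SD 0.15), with Cdx2 at 0.23, Epcam at 0.13, Cldn7 at −0.01 and Cdh1 at −0.06. Red blood cell and enteric glia markers had 0 and 2 measured genes and were not given a value. All these lists lay within the range of the control gates, which is shifted by the cells those gates took. The median number of genes per cell at the thinned depth was 6833 with and 7036 without Mex3a, a difference of −203, while control gates gave a median difference of 549, and 15 of 200 gave −203 or less.

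Among single genes, those with the highest ratios in cells with Mex3a were BC005624 (77.3 against 29.8 CPM, log2 ratio 1.35, SD 0.98), Zbtb1, a zinc finger protein (64.8 against 26.6 CPM, 1.26, SD 0.90), Necap2, an endocytosis adaptor (54.8 against 26.4 CPM, 1.02, SD 0.92), Klhl24 (70.6 against 36.03 CPM, 0.95, SD 1.91), Dhdds, a dolichol synthesis enzyme (111 against 57.1 CPM, 0.94, SD 0.67), and Lipt2, which acts in lipoic acid synthesis (132 against 73.4 CPM, 0.84, SD 0.69). Wt1os (1.19), an antisense gene, and the processed pseudogenes Gm16053 (1.09), Gm6341 (0.85) and Gm14270 (0.84) are uncertain, since strand and shared reads are not resolved. The rule that picked these genes asked for the same direction in at least 8 of 9 sets. The genes lowest in cells with Mex3a had almost no counts there. St6galnac6, a sialyltransferase, had 0 counts against 130, with an exact upper limit of −1.93 for the log2 ratio, and the vomeronasal receptor gene Vmn2r94 had 0 against 99, with an upper limit of −1.53. With 1 count in cells with Mex3a, the depth-scaled log2 ratio of summed counts was −4.30 (−9.61 to −1.80) for Ankrd16, −4.21 (−9.53 to −1.72) for 4632415L05Rik, −3.92 (−9.24 to −1.42) for the growth factor gene Igf1, −3.73 (−9.05 to −1.23) for Gm19705 and −3.63 (−8.95 to −1.13) for Sec14l4. The antisense genes Gm17529 (−3.61, −8.92 to −1.10) and Gm16638 (−3.66, −8.98 to −1.15) and the pseudogene Sms-ps (−3.59, −8.91 to −1.09) are uncertain. These genes were picked as extremes of 14256 genes, so their values are biased away from 0, and the intervals do not allow for the choice of draw. The highest ratios were smaller than those of other gates. At rank 10 from the top Mex3a had 0.84, and 0 of the 13 control gates with a value in 8 or 9 sets lay lower (median 1.90). At rank 10 from the bottom Mex3a had −2.77 against a median of −2.55 in those gates, of which 2 lay lower. As for the lists, control gates are a skewed comparison, since they tended to take cells with more genes. They do not give a level of chance. Over 20 other draws of the thinning Igf1 ranged from −1.36 to −0.53 and Vmn2r94 from −3.46 to −0.01, on the scale with a pseudocount.

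Mex3a was also compared across the whole range of the cell cycle score, in tertiles of 114 cells. The lowest, middle and highest tertiles had 257, 329 and 355 CPM of Mki67. The share of cells with Mex3a at the thinned depth was 8.77% (4.29 to 15.5), 7.89% (3.67 to 14.5) and 12.3% (6.88 to 19.7), and mean Mex3a was 7.43, 7.11 and 7.48 CPM. The log2 ratio of Mex3a CPM between the highest and the lowest tertile was 0.01, against an SD over sets of 1.96. The parts of the score pointed in opposite directions. By the G2 and M phase list alone the ratio was 0.44 (6.15 and 8.71 CPM, and 7.02% and 13.2% of cells, in the lowest and highest tertile), and by the S phase list alone it was −0.57 (9.36 and 5.99 CPM, and 13.2% and 11.4% of cells). The intervals of these shares overlap, and both ratios were smaller than the SD over sets of the full score. That SD rests on few cells with Mex3a in each set, so differences of this size are not excluded. The score is a range and the tertiles are not cell types, with 21 and 22 cells within 0.1 of the lower and upper boundary. Median total counts were 30525, 31924.5 and 38066.5.

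**Figure D3:**
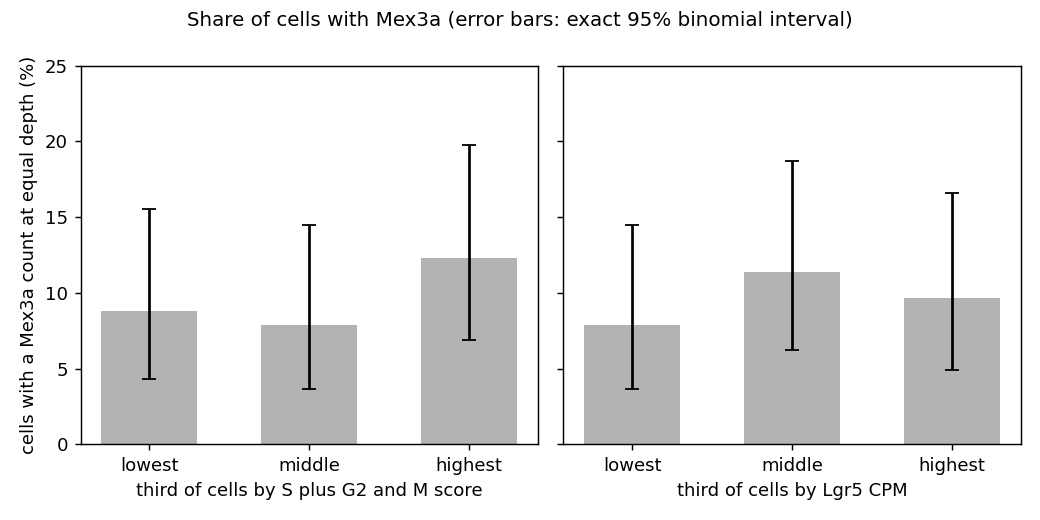
Share of cells with a Mex3a count at the thinned depth (y axis, percent; error bars are exact 95% binomial intervals) in tertiles of 114 cells by cell cycle score and by Lgr5 CPM (x axis, from lowest to highest). The shares run from 7.89% to 12.3% and their intervals overlap.

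Clustering without Mex3a gave 3 clusters, and Mex3a did not separate them. The first (167 cells) was led by Gm10913, Gm3571, Zfp623, Gdf15, Mbip, Gm2991, Gm13552, Gm6123, Gm13910 and Ring1, each with a mean of at most 1.31 counts. The second (126 cells) was led by Ston1, Gm3183, Gm2916, 4933438K21Rik, Gm26837, Gm17017, Rhox4a2, Lpar4, Gm3002 and Gm26315, and had a median of 9628 genes per cell against 8249 in other cells, at median totals of 30525 and 33408. The third (87 cells) was led by genes of Paneth cell granules, the defensins Defa-ps1, Defa-ps10, Defa5, Defa28, Defa34, Defa27, Defa35, Defa31 and Defa25 and the pentraxin Mptx2. Its Paneth list had a log2 ratio of 1.69 over other cells and its mean Lyz1 was 14.01 counts, yet its cells had means of 6.46 Lgr5 and 7.25 Olfm4 counts, so it was left unnamed. Defensin genes are close copies of one another, so the split of counts between them is uncertain, and this cluster held 1 to 17 cells per library set. The other 2 clusters had no cell type marker among their leading genes and were also left unnamed. Mex3a had a count in 12.6% (7.96 to 18.6), 11.1% (6.21 to 17.9) and 13.8% (7.34 to 22.8) of cells of the 3 clusters, with means of 7.41, 7.99 and 9.07 CPM. The number of clusters depended on the settings.

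Markers of other cell types were counted in each kept cell. At least 3 markers with 1 count or more were present in 100% of cells for enterocytes, 99.2% for Paneth, 89.5% for goblet, 63.9% for immune, 41.8% for tuft, 8.68% for endothelial, 5.53% for enteroendocrine and 4.21% for stromal cells, and in 1 cell for enteric glia. At least 1 of the immune, stromal, endothelial and glia lists met this in 66.3% of cells. With 3 markers at 10 counts or more, these shares were 17.1% for enterocytes, 30.8% for Paneth, 2.63% for goblet, 0.526% for immune and 0.526% for tuft cells, and 0 of 380 cells for each of the other lists, which allows a share of up to 0.789% at a floor of 3 cells and 0.966% by the exact interval. The most widespread genes of the Paneth list were Defa24 (mean 18.5 counts, in 100% of cells), Itln1 (8.25 counts, 99.2%), Lyz1 (7.07 counts, 95.5%) and Defa17 (8.29 counts, 93.4%), and the most abundant genes of the enterocyte list included Prap1 (12.9 counts) and Fabp2 (6.63). Of the immune list, Cd74 (6.15 counts) and H2-Aa (5.13), genes of antigen presentation that intestinal epithelium also uses, were in 95% and 94.5% of cells. Lyz2, Cd52 and Ptprc followed, in 34.7%, 31.1% and 28.4% of cells, while Cd3e (0.142), Tyrobp (0.0263) and Cd79a (0.0105) were rare. Of the red blood cell list, 1 gene, Alas2, was in the table, with a count in 4.47% of cells.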

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

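The tests of exchange within a set and of free RNA were chosen after the shares of some cell type markers within and between sets had been seen, though before those of all genes, the test of exchange between sets was chosen before its result was seen, and the marker Trpm5 was chosen after its values were seen. Of 55 quantities compared over the 10 library sets, mostly means of named genes and gene lists, 3 had a set far from all others, and chance flags about 1 in 20 such groups. The mean count of Dclk1, a tuft cell gene, was 2.89 in set 1 and 0.590 to 1.65 in the other sets. The mean over the tuft cell list was 1.58 in set 1 and 0.379 to 0.644 elsewhere. The mean count of Muc2, the main mucin of goblet cells, was 3.56 in set 4 and 0.0256 to 1.05 elsewhere.

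Set 1 held a cell with 20 counts of Dclk1 and a cell with 17 of the tuft cell channel gene Trpm5, set 4 held a cell with 23 counts of Muc2, and the other cells of those sets often had a few counts of the same genes: Muc2 was in 89.5% (75.2 to 97.1) of the other cells of its set and 26.1% (21.5 to 31.1) of cells in other sets, and Trpm5 in 70.3% (53.02 to 84.1) and 6.73% (4.31 to 9.92). Barcodes exchanged between sets are argued against, since 49.0% of 626 genes with 10 counts or more in 1 cell and none in at least 80% of cells (307 genes) were in a higher share of cells with the same barcode number in other sets. Free RNA spread evenly over the chip is argued against as the whole source, since these genes were in 20.2% of cells of the same set and 10.97% of other cells, a ratio of 1.84. What stays open is an exchange of molecules or barcodes within a set, which may place a few counts of an abundant transcript in neighbouring cells: 82.4% of the genes (516) were in a higher share of the same set, as it predicts. No biological explanation was tested, since the design has 1 group, and for Mex3a itself the shares were 15.8% (6.02 to 31.3) in the set of its top cell and 11.7% (8.51 to 15.6) in other sets.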

How the results depend on the processing

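The 20 random draws, the counts mapped back through merged identifiers, the Mki67 threshold of 5 counts and leaving out a cluster or cells rich in other markers were chosen after the results were seen. Of the values that answer a comparison, 279 moved by less than the spread between library sets or the counting interval, 12 moved by more and 1 reversed (a value outside the control gate range that changed sign). Among other values 1735, 74 and 1 did so. These counts include alternatives on gene number and mitochondrial share that changed no cell and could not move. Leaving out 1 set keeps most cells. Sign changes inside the control gate range do not count as reversed. The sign held in 7 of 20 alternatives for Mex3a between cell cycle tertiles, 20 of 29 for stem cell genes, 14 of 29 for brakes, 23 of 29 for S phase and 27 of 29 for G2 and M phase genes. With Mex3a at 3 counts or more as the gate (12 against 300 cells) the fatty acid oxidation list was −0.030 and Gm16638 was 0.20, both reversed, and the share of cells with Mex3a was 3.42%; fewer cells pass that gate. The G2 and M phase list was −0.030 with thinning to the 25th percentile and −0.048 without the cluster with the most genes (26 against 206 cells), and the Mki67 log2 ratio was 0.12 with counts mapped back; the cause was not tested. With 5 counts or more, the difference in Mki67 shares was −6.38 points. Clusters numbered 8 at resolution 1, 5 with 2000 variable genes and 5 with 10 principal components. Cells with 3 markers of an immune, stromal, endothelial or glia list, 66.3% in all, were 9.74% with 5 markers, 13.4% with 3 markers at 3 counts and 52.6% after thinning, and a minimum of 50000 counts kept 12 cells; these follow from stricter limits. Leaving out each library set gave −0.03 to 0.07 for the S phase list, 0.05 to 0.12 for the G2 and M phase list, 0.14 to 0.19 for ribosome biogenesis, 0.09 to 0.18 for fatty acid oxidation, −0.06 to 0.02 for stem cell genes, −0.01 to 0.11 for Lgr5 and 11.7% to 13.1% for the share of cells with Mex3a. Ribosome biogenesis was above 0 in all 29 alternatives (0.03 to 0.26) and in all 20 draws (0.07 to 0.22), and fatty acid oxidation in 28 of 29. The log2 ratio of Mex3a between cell cycle tertiles ran from −0.92 to 0.46 in 20 alternatives. Spike-in scaling was not run, since no spike-in was in the table, leaving out cells with 3 markers of any other list left 0 cells, and the minimum of 2000 genes and the mitochondrial limit removed no kept cell. Depth limits the Mex3a gate: a count of 1 decides the class of most cells, and other draws placed 30 to 37 cells in the class with Mex3a.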

Other observations

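The comparisons of gene lists across tertiles and the tests of merged identifiers, read depth, pairs of cells, stromal or endothelial cells and the Mex3a share of a cluster were chosen after the results were seen, while the test of the receptor gene share was chosen before. Early-response and heat shock genes were compared between cells with the most and the least Lgr5. The dissociation and stress list had a median log2 ratio of −0.27 in the highest over the lowest Lgr5 tertile (15 of 15 genes below 0, lower in 9 of 10 sets, SD 0.21). The AP-1 subunit genes Fosb (104 against 159 CPM, −0.60) and Fos (317 against 369 CPM, −0.22), the RNA decay factor Zfp36 (−0.34), Atf3 (−0.30) and Egr1 (205 against 246 CPM, −0.27) were among them. Without the cluster with the most genes the median was −0.18 (13 of 15 below 0, lower in 8 of 10 sets, SD 0.32), smaller than its spread. Stem cell genes other than Lgr5 had a median of 0.14 (18 of 21 above 0), no larger than its spread (SD 0.14), from the ephrin receptor Ephb3 at 0.53 and Olfm4 at 0.23 to Axin2 at −0.04 and Ascl2 at −0.12. Markers of 3 other cell types had larger medians with a wider spread, and those of Paneth, endothelial, enteroendocrine and immune cells lay at −0.0025, −0.03, 0.06 and 0.16. The larger medians were 0.76 for stromal (5 of 5 above 0, SD 1.33), 0.59 for tuft (8 of 9, SD 0.60) and 0.39 for enterocyte genes (8 of 12, SD 0.41). Of 10 sets, the stromal list was higher in 7 and lower in 2, the tuft list in 3 and 2, and the enterocyte list in 7 and 3. Without the cluster with the most genes these were 0.78 (SD 0.73), 0.37 (SD 0.95) and −0.0021 (SD 0.18). Goblet cell genes had a median of −0.49 (8 of 10 below 0, lower in 7 of 10 sets, SD 0.24), with Tff3 at 97.8 against 138 CPM and Fcgbp at −0.85, and −0.68 without the cluster with the most genes (SD 0.59, lower in 5 of 10 sets and higher in 4). The lowest and highest tertiles had median totals of 33753.5 and 32312 counts.

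Across the cell cycle score, markers of some other cell types were lower in the highest than in the lowest tertile, while Paneth (−0.05, SD 0.73) and immune genes (−0.13, SD 0.65) lay nearer to 0. The medians were −1.44 for endothelial (lower in 10 of 10 sets, SD 0.82), −0.98 for tuft (lower in 4 sets, higher in 2, SD 0.83), −0.91 for stromal (7 and 2, SD 1.42), −0.86 for enteroendocrine (5 and 2, SD 0.78), −0.61 for goblet (7 and 3, SD 0.70) and −0.55 for enterocyte genes (5 and 4, SD 0.41). Those of the stromal and goblet lists were smaller than their spread. Without the cluster with the most genes they were −0.34, 0.29, 0.16, −0.19, −0.21 and −0.03. Ribosome biogenesis genes were higher by a median of 0.30 (20 of 22 above 0, higher in 10 of 10 sets, SD 0.12), with Wdr12 and Gar1 at 0.60 and 0.59 and the nucleolar gene Gnl3 at 0.48. Without the cluster with the most genes this median was 0.07 (13 of 22 above 0). Genes of the mitochondrial genome were lower, at −0.23 (12 of 15 below 0, lower in 10 of 10 sets) and at −0.20 without the cluster. The lowest and highest tertiles also differed in depth, with median totals of 30525 and 38066.5 counts. Stem cell genes lay at 0.02, with Ascl2 at 0.53 and Lgr5 at −0.21, and at −0.11 without that cluster (17 of 22 below 0, lower in 8 of 8 sets, SD 0.17). Epithelial genes (−0.16, 7 of 8 below 0) and ribosomal protein genes (−0.18, 77 of 85 below 0) were also lower there. The shift is thus smaller than its spread and not particular to stem cell genes. Both of the following were chosen after their values were seen: Ctla4, an inhibitory receptor gene of T cells, had a median of 19 counts in the 400 cells (range 2 to 28), and the glycolysis enzyme Gapdh had a median of 0 and at most 4. Both values are odd for intestinal stem cells, and an error of counting or annotation in the deposited table was not excluded, since that needs the reads. This doubt extends to the value of any single gene.

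Counts of abundant genes levelled off near 30, with a mean of 30.3 for mt-Rnr2 and a maximum of 36 in the table. Too few reads per cell are argued against, since sampled reads vary at least as much as their mean and the ratio of variance to mean for mt-Rnr2 was 0.113. Identifiers of 5 bases merged at up to 2 mismatches, simulated for 5000 molecules, levelled off at 30.4 with a maximum of 36, while 3 other simulated schemes levelled off at 46.5, 165 and 88.1. A merging of similar identifiers may thus have set the scale, as a hypothesis found and tested on the same data, and other counting steps that saturate stay open. No biological explanation was tested.

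The second cluster had more genes per cell (9628 against 8249) at a lower median total (30525 against 33408), with stromal genes at a log2 ratio of 1.64 and endothelial genes at 2.10 over other cells. Tuft (0.88), immune (0.51), enterocyte (0.49) and enteroendocrine genes (0.40) were also higher, while goblet (−0.06) and Paneth genes (−0.41) were not. Counts spread over silent genes, as from genomic DNA, may account for part of the higher number of genes. The 570 olfactory and vomeronasal receptor genes took 0.117% of counts against 0.0292% in other cells, a ratio of 4.02. This cluster was picked for its number of genes, and receptor genes could enter the clustering. A higher receptor share follows in part from that choice and does not tell genomic DNA from other sources of spread counts. Pairs made of 2 cells like the other cells carry at most the counts of both. Receptor gene counts per cell were 3.70 times those of other cells (SD over sets 1.03), more than such pairs would carry on average. The cells were grouped in part by such counts, so this ratio cannot decide against pairs. The receptor counts of a partner of another type were not measured, so pairs of both kinds stay open. Diffuse counts as the whole source of Mex3a are argued against, since its share of cells did not rise as the receptor counts did. That share was 11.1% (6.21 to 17.9) in the cluster and 12.99% in other cells, a ratio of 0.855. The interval also allows a higher share in the cluster than in other cells. Mean Mex3a was 0.270 counts per cell in this cluster (0.187 to 0.377), against 0.251 and 0.230 in the other clusters. Diffuse counts as the source of a part of the Mex3a counts are thus not excluded. Stromal or endothelial cells captured alone, which the sort for the Lgr5 reporter should leave out, are argued against, since Epcam was in 100% of the cluster's cells at 0.802 times its mean count in other cells (13.1 against 16.3, SD of the ratio over sets 0.0874), with a mean of 6.48 Lgr5 counts. A share of the stromal and endothelial counts from partner cells of these types stays open. Mean counts were 1.71 for Pecam1 (0.346 in other cells) and 0.0714 for Vim (0.0197 in other cells), which such cells express strongly. No biological explanation was tested, since the design has 1 group.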
